A study of Allium sativum with 18 samples.

How the data were processed

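RNA was measured in basal and storage clove of garlic bulbs at 3 stages, with 3 biological replicates per group per the labels and the series design. Libraries were made from total RNA with an Illumina library kit, per the labels' protocols. The authors deposited 1 table of FPKM values (fragments per kilobase of gene model, scaled to the mapped fragments of the library) with 1 column for each of the 18 libraries, per the file headers. The submitters' processing notes name HISAT2, without a version. The read counter, the genome build, the annotation and whether strand was used are not given in the sources used here. The table holds 57561 gene IDs, of which 16255 are at 0 in every library, and 1 empty column. It pairs none of the IDs with a name or description. Gene lists for flavour precursors, fructans, hormones and other pathways, their set tests and an enrichment of annotation terms had been fixed in advance on protein descriptions, and could not be run for that reason.

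The depth of each library was recovered from the values. An FPKM value is a whole number of reads divided by the length of the gene model and the library total, so values of a gene rise in steps. The steps gave library totals at which the lengths of 400 genes came out whole, with a mean deviation of 1.23e-06 bp, against 0.25 bp at the other totals tried. With these totals and the smallest whole length that served each gene, 100% of the 595800 values above 0 were whole within 0.01 reads. Because the length was searched for, part of that agreement comes from the search. The reads recovered sum to 99.99% of each total, so the totals count reads assigned to genes. Whether a unit was a single read or a pair of reads is not given in the sources used here, and it is called a read throughout. Among the 21276 genes with over 100 reads in a library, 95.2% had a length that is a multiple of 3, so the length is a coding length. Library totals were 6540146 to 21897520 reads. For a coding length of 1 kb, 3 reads correspond to 0.137 FPKM in the deepest library and 0.459 FPKM in the shallowest. Such floors and the 95% interval given for 1 ratio (exact, from the binomial distribution of the reads) cover counting error only.

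The test was made on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3. Genes with an FPKM of at least 1 in at least 3 libraries were kept, 30530 in all. One linear model of the 6 group means over all 18 libraries (12 residual degrees of freedom, with a trend of the variance in mean expression, 3.8 prior degrees of freedom) gave 11 comparisons: basal against storage at each stage, each pair of stages in each tissue, and 2 interactions of tissue and stage. P-values were adjusted by the Benjamini-Hochberg method within a comparison, and genes with an adjusted p below 0.05 were called. A change on this scale understates the change of genes with low values, so group means in FPKM are given beside it. Genes named by ID were the 2 with the largest rise and the 2 with the largest fall among called genes whose 3 values in one group all exceeded the 3 in the other and whose higher group mean was at least 10 FPKM, in the 3 tissue comparisons and the 4 comparisons of consecutive stages. The rule, fixed with the groups, tests and most alternatives before the data were examined, had asked for 5 each way and for an informative description, and was reduced to 2 because the IDs carry no names. Other IDs in the text were chosen after their values were seen, as the most abundant transcripts. Overlaps of gene lists were set against the product of the list sizes divided by the genes tested. All calls use the same estimate of the spread of a gene, so a gene with a small spread tends to be called in each comparison. The product may therefore be a low reference for an overlap.

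The model was tested on simulated data. Counts were drawn for the real genes from their mean share of the reads, the real library totals and their spread within groups, with 200 genes changed in 1 group. In basal against storage at dormancy, with 29877 genes passing the filter, 59% of the genes changed 2-fold and 84% of those changed 4-fold were recovered, and unchanged genes made up 6.5% of the calls. In dormant against enlarging storage clove (29885 genes) the shares were 67% and 88%, with unchanged genes making up 12.4% of the calls. In the interaction from enlarging to dormant (29857 genes) they were 38% and 72%, with 6.8%. The simulation gave each gene the same spread in all groups. The real comparisons of 2 groups called 20.3% to 70.3% of the genes tested, far more than 200 genes. Recovery and the share of unchanged genes both depend on how many genes change, so the simulated shares do not carry over to the real calls.

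Replicates were compared before averaging. With reads pooled over genes with at least 20 reads in a pair, the chi-square per gene was between 2.68 and 65.92 for the 18 pairs of replicates, so no pair agreed within sampling noise and each library counted as 1 replicate. The alternatives were median-ratio scaling, quantile normalization, a pseudocount of 0.1, no filter (41306 genes), an FPKM of at least 5 in 3 libraries (23245 genes), no variance trend, a fit on only the groups compared, the replicate number as a block, array weights, an added threshold of 1 on the log2 change, and leaving out each library in turn. Another 3 were added after the depths and the positions of the libraries were seen: voom weights on the recovered reads, thinning every library to the 6539512 reads recovered in the shallowest, and leaving out storage enlarging replicate 2 together with basal germinating replicate 3. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.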

Results

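Gene expression was measured by RNA sequencing in the bulbs of garlic (*Allium sativum*), in plants labelled Chalingzipisuan. Each bulb was separated by hand into basal clove and storage clove. Bulbs were taken at 3 stages: while they were enlarging, while they were dormant, and at germination, when the shoots were still short. Tissue and stage together made 6 groups of 3 biological replicates, 18 libraries in all. Expression was given as FPKM for 57561 gene IDs, of which 41306 had a value above 0 in any library. The reads assigned to genes came to between 17933342 and 19335572 per library in basal enlarging clove, 19611684 and 20897436 in basal dormant clove, and 18579917 and 21897520 in basal germinating clove. Fewer reads were assigned to genes in storage clove at every stage, 11600094 to 12747904 reads when enlarging, 6540146 to 7155009 when dormant and 10383944 to 12988262 when germinating. The number of assigned reads therefore differed between the tissues at each stage, most of all at dormancy, where basal libraries held on average 2.93 times the reads of storage libraries. The files do not pair the gene IDs with gene names, so genes are given below by ID only, with at most 2 that were higher and 2 that were lower in each comparison.

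The libraries grouped by tissue and by stage. Spearman correlations of log2(FPKM + 1) lay between 0.944 and 0.989 for the 18 pairs of replicates, and between 0.651 and 0.964 for the 135 pairs from different groups. The first principal component held 42.4% of the variance and set the germinating libraries apart from the others, and the second held 36.2% and separated basal from storage clove. Enlarging and dormant clove of the same tissue were the most similar groups, with a median correlation of 0.953 in basal and 0.948 in storage clove. Germinating basal and dormant storage clove were the least similar, with a median correlation of 0.685. A pair of libraries lay nearer to the other tissue than their replicates did. Storage enlarging replicate 2 correlated with the basal enlarging libraries at a mean of 0.895, against 0.868 and 0.857 for its replicates, and basal germinating replicate 3 correlated with the storage germinating libraries at 0.829, against 0.798 and 0.778. The most abundant transcript was Asa6G06669.1 in each of the 12 enlarging and dormant libraries, at 7033.4 to 10336.6 FPKM. At germination it was Asa3G01406.1 or Asa4G02790.1 in basal clove and Asa2G05973.1 in storage clove.

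**Figure D1:**
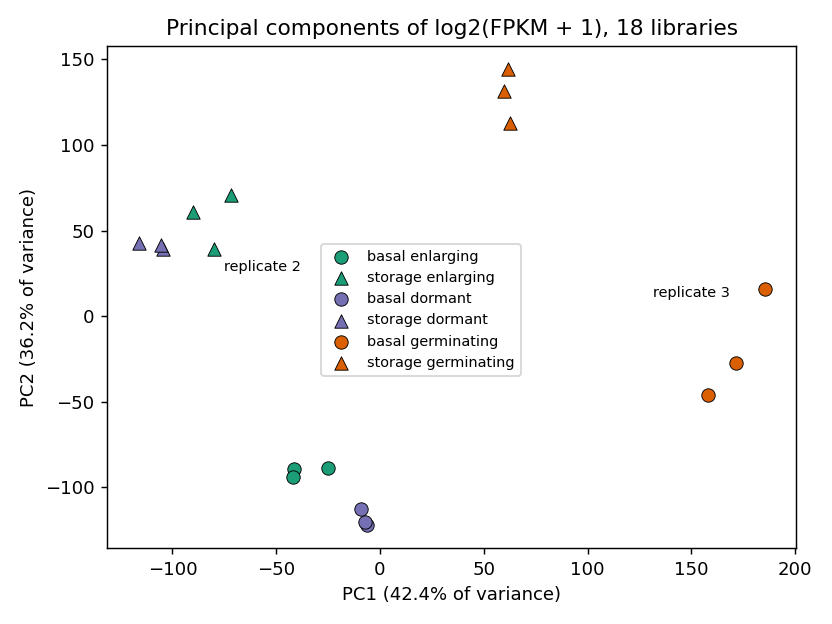
First 2 principal components of log2(FPKM + 1) over 30530 genes, 1 point per library, circles for basal and triangles for storage clove, coloured by stage. Germinating libraries lie at the right on PC1 (42.4% of the variance), basal and storage libraries part on PC2 (36.2%), and the 2 marked libraries lie toward the other tissue.

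The first question was how basal clove differed from storage clove while the bulb was enlarging. Asa4G00942.1 reached 252.5 ± 28.1 FPKM in basal clove and 4.06 ± 2.29 in storage clove (mean ± SD, n = 3 libraries each here and below), a 62.2-fold difference, and Asa5G00519.1 reached 222.1 ± 43.0 against 3.87 ± 2.97 FPKM, 57.3-fold. In the other direction, Asa0G01738.1 stood at 2459.9 ± 199.8 FPKM in storage clove and 25.2 ± 7.74 in basal clove, 97.7-fold lower in basal, and Asa2G02061.1 at 135.3 ± 43.6 against 0.517 ± 0.232 FPKM. These 4 genes differed by 5.75, 5.69, -6.60 and -6.45 on the log2(FPKM + 1) scale, with limma adjusted p-values between 5.5e-11 and 2.3e-08. Over all 30530 genes tested, 15724 passed the adjusted threshold, 8757 of them higher and 6967 lower in basal clove. Of these, 4093 were higher and 2030 lower by at least 1 on the log2 scale. The share of called genes that were higher in basal clove was 55.7% and became 45.5% after quantile normalization, which moved the median difference of all genes from 0.06 to -0.06.

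At dormancy the tissues differed in more genes. Asa7G06825.1 was at 235.5 ± 4.70 FPKM in basal clove and 0.392 ± 0.358 in storage clove, where 5 reads were counted over the 3 libraries, and Asa2G00397.1 was at 605 ± 90.6 against 3.55 ± 2.71 FPKM. Their log2 differences were 7.44 (SE 0.43, limma adjusted p = 6.5e-10) and 7.21 (SE 0.36, limma adjusted p = 1.7e-10). The genes named as lower in basal clove, by their difference in log2(FPKM + 1), were Asa6G05443.1, at 0.519 ± 0.411 FPKM against 129.7 ± 8.66 in storage clove, and Asa7G03275.1, at 7.39 ± 1.66 against 592 ± 226.3. In all, 17615 genes were called, 10557 higher and 7058 lower in basal clove, and 5672 and 2185 of them by at least 1 on the log2 scale, or 4078 and 3663 after quantile normalization. At this stage 949 genes were higher in basal clove by 3 or more on the log2 scale and 128 were lower by as much, or 2245 and 350 with voom on the recovered reads. The share of calls higher in basal clove was 59.9%, against 43.0% after quantile normalization, when the median difference of all genes went from 0.10 to -0.16.

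At germination the largest tissue differences on the log2 scale were higher levels in basal clove. Asa0G00573.1 reached 2128.4 ± 166.7 FPKM in basal and 7.56 ± 1.29 in storage clove, 281.6-fold, and Asa4G01059.1 reached 1608.5 ± 369.6 against 6.66 ± 0.682, 241.6-fold. Both had also been higher in basal clove before germination, Asa4G01059.1 at 101.5 ± 13.7 FPKM in dormant basal clove against 4.09 ± 2.26 in dormant storage clove. Asa5G04732.1, at 0.716 ± 0.468 against 71.1 ± 18.4 FPKM, and Asa8G03949.1, at 4.78 ± 6.87 against 85.9 ± 30.7 FPKM, were lower in basal clove, by -5.40 (SE 0.25, limma adjusted p = 7.2e-11) and -4.60 (SE 0.70, limma adjusted p = 2.9e-05) on the log2 scale. The basal mean of Asa8G03949.1 rests mostly on replicate 3, at 12.7 FPKM, against 1.45 and 0.212 FPKM in replicates 1 and 2. Differences of 3 or more on the log2 scale were found for 1167 genes higher in basal clove and 35 lower, or 2465 and 165 with voom on the recovered reads. Of all 18457 genes called, 7636 were higher and 10821 lower in basal clove with the deposited values, and 8828 higher and 8769 lower after median-ratio scaling, so that the share of higher genes was 41.4% or 50.2%. Quantile normalization gave 7050 higher and 12522 lower, a share of 36%. The median difference of all genes was -0.16 with the deposited values, -0.05 after median-ratio scaling and -0.26 after quantile normalization.

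**Figure D2:**
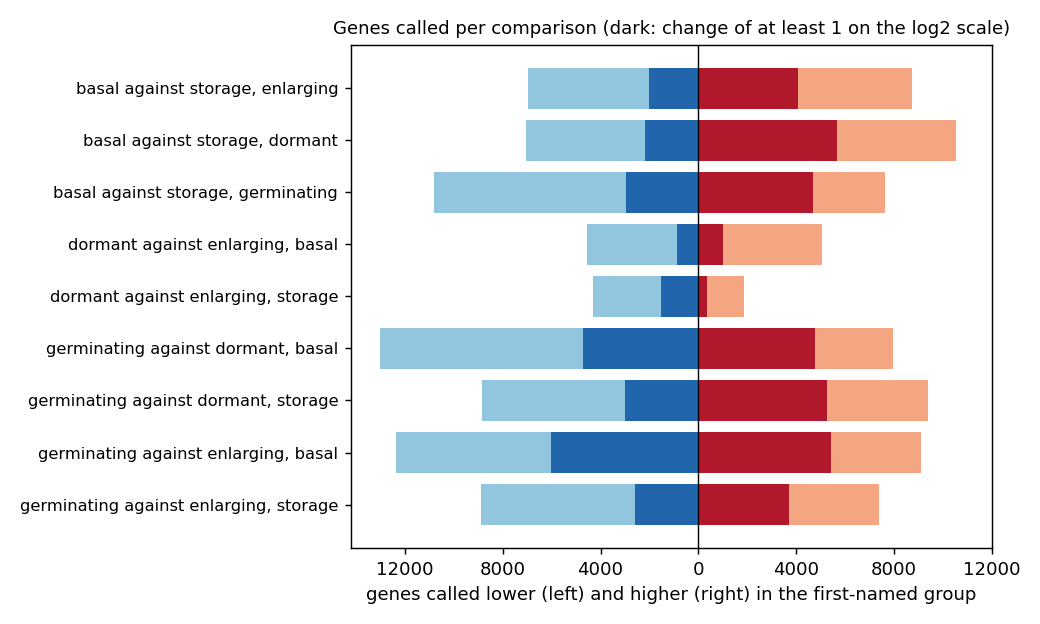
Number of genes called at an adjusted p below 0.05 in the 9 comparisons of 2 groups, higher in the first-named group to the right and lower to the left, with dark bars for genes that also changed by at least 1 on the log2 scale. The comparisons of dormant with enlarging clove hold the fewest calls, 9615 in basal and 6185 in storage clove.

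The tissue differences recurred across stages. The 3 tissue comparisons share no library, though they share the estimate of the spread of each gene, which may make 757 a low reference. At all 3 stages 4290 genes were higher in basal clove, against 757 if the lists were independent. Fits on only the groups compared, which share no such estimate, gave 3957 genes higher and 3076 lower at all 3 stages. With the fit on all libraries another 3351 genes were lower at all 3 stages, against 571. Which list was longer depended on the scaling, with 3382 genes higher, against 433, and 4637 lower, against 1218, after quantile normalization. Asa4G00942.1 was one gene of this kind, at 428.6 ± 44.8 FPKM in dormant and 393.5 ± 81.1 in germinating basal clove and at 7.78 ± 1.55 and 7.80 ± 2.64 in storage clove. The genes higher at all stages were 49.0% of those called higher in enlarging basal clove. Across genes, which are not independent replicates, the tissue differences correlated at r = 0.79 between enlarging and dormant bulbs and at r = 0.61 between dormant and germinating bulbs. Genes called in opposite directions numbered 864 between enlarging and dormant bulbs, against 4434 for independent lists. They numbered 1565 between dormant and germinating bulbs, against 5507, and 1541 between enlarging and germinating bulbs, against 4846.

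The stage comparisons asked what changed as bulbs went from enlarging to dormant and from dormant to germinating. From enlarging to dormant, basal clove showed few changes above 3 on the log2 scale. Asa7G01918.1 rose from 3.06 ± 4.98 to 41.3 ± 14.9 FPKM and Asa7G06203.1 from 1.11 ± 1.69 to 26.8 ± 11.2 FPKM, or by 4.10 (SE 0.69, limma adjusted p = 0.00034) and 3.93 (SE 0.49, limma adjusted p = 3.1e-05) on the log2 scale. Both enlarging means rest mostly on replicate 1, at 8.8 and 3.07 FPKM. Replicates 2 and 3 were at 0.362 and 0 FPKM for the former gene and 0.166 and 0.104 for the latter. Over the alternatives the log2 changes ranged from 3.47 to 5.74 and from 3.6 to 6.03. Asa7G03238.1 fell from 653.4 ± 150.3 to 73.6 ± 21.8 FPKM, 8.87-fold. Asa7G02774.1 fell from 13.4 ± 5.54 to 0.601 ± 0.169 FPKM, but was no longer called when the recovered reads were weighted by voom (adjusted p = 0.053, the highest of its 30 alternatives). Of 9615 genes called, 5042 rose and 4573 fell. Changes of at least 1 on the log2 scale made up 1877 of these, 1019 upward and 858 downward, and 5 genes rose and 4 fell by 3 or more. With voom on the recovered reads, a scale that compresses low values less, 1606 rose and 1218 fell by at least 1, and 41 rose and 58 fell by 3 or more.

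In storage clove the same step lowered more genes than it raised. Asa7G06203.1 rose here too, from 0.611 ± 0.808 to 147.3 ± 8.56 FPKM, and the gene with the next ID, Asa7G06204.1, rose from 0.725 ± 0.927 to 129.9 ± 6.67 FPKM. Their log2 changes were 6.63 (SE 0.49, limma adjusted p = 2.4e-07) and 6.37 (SE 0.47, limma adjusted p = 2.1e-07). Asa5G02473.1 fell from 134.4 ± 17.4 to 0.576 ± 0.539 FPKM, where 5 reads were counted. Asa2G00496.1 fell from 35.8 ± 1.53 FPKM to 1 read over the 3 dormant libraries, a ratio of 721 per unit of depth with a 95% counting interval of 129 to 28500. Of 6185 genes called, 1876 rose and 4309 fell, and by at least 1 on the log2 scale 340 rose and 1522 fell. Over all calls the excess of falls depended on the scaling, while at 1 or more on the log2 scale 402 rose and 1323 fell after median-ratio scaling and 457 rose and 1108 fell after quantile normalization. The share of calls that rose was 30.3% with the deposited values, 48.9% after median-ratio scaling and 51.1% after quantile normalization, which moved the median of all genes from -0.07 to 0 and to 0.05. Weighting the recovered reads by voom reduced the calls to 3626, 1340 up and 2286 down.

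Germination changed both tissues far more. In basal clove Asa5G00575.1 rose from 0.166 ± 0.179 FPKM (8 reads over the 3 dormant libraries) to 2071.6 ± 501.2 FPKM, and Asa2G05915.1 rose from 1.19 ± 0.304 to 2808.1 ± 1521.4 FPKM, or by 10.78 (SE 0.55, limma adjusted p = 1.7e-10) and 10.18 (SE 0.56, limma adjusted p = 3.5e-10) on the log2 scale. Asa6G03213.1 fell from 221.3 ± 87.8 to 1.01 ± 0.475 FPKM, 218.3-fold, and had stood at 1274.2 ± 203.1 FPKM in enlarging basal clove. Asa7G01747.1 fell from 272.7 ± 55.7 to 4.61 ± 3.12 FPKM, 59.1-fold. Of 20998 genes called, 7963 rose and 13035 fell. By 3 or more on the log2 scale 966 genes rose and 67 fell (2282 and 306 with voom on the recovered reads), and 4762 rose and 4705 fell by at least 1. The median change of all genes was -0.27 with the deposited values and -0.03 after median-ratio scaling, which put the share of calls that rose at 52.4% in place of 37.9% and the changes of at least 1 at 5928 up and 2485 down.

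In storage clove at germination, Asa6G00720.1 rose from 3.02 ± 2.35 to 4603.6 ± 1834.1 FPKM and the gene with the next ID, Asa6G00721.1, from 2.18 ± 2.53 to 2856.7 ± 1168.4 FPKM. The log2 changes were 10.27 (SE 0.65) and 10.02 (SE 0.64), each with a limma adjusted p of 1.3e-09. Both stayed called in all 30 alternatives, with limma adjusted p-values as high as 0.016 and 0.026. Whether reads were shared between such neighbouring IDs is not given in the sources used here. Asa2G05822.1 fell from 4054.4 ± 178.4 to 9.20 ± 2.40 FPKM, 440.6-fold, and Asa7G03238.1 from 2068.5 ± 719 to 6.37 ± 0.843 FPKM, 324.8-fold. Of 18234 genes called, 9392 rose and 8842 fell, 5279 and 2997 of them by at least 1 on the log2 scale, or 4310 and 4006 after quantile normalization. Quantile normalization changed the share of calls that rose from 51.5% to 40.9% and the median change of all genes from 0.01 to -0.17.

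**Figure D3:**
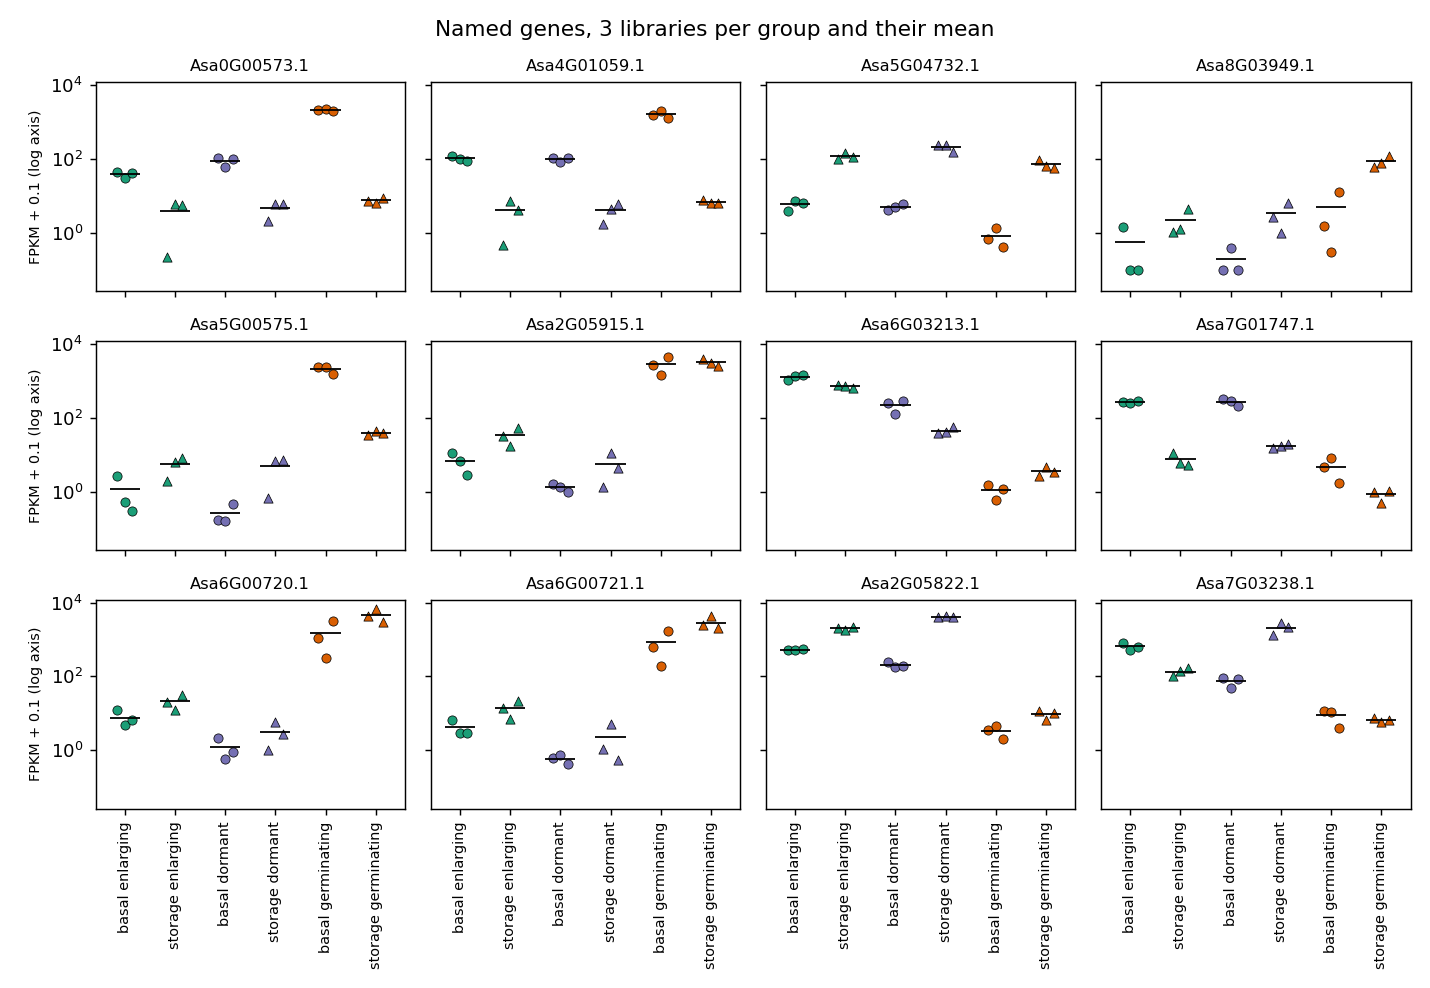
FPKM + 0.1 on a log axis for the 12 genes named at germination, 1 point per library (circles basal, triangles storage) and a line at the mean of each group of 3. Asa5G00575.1 stands at 2071.6 FPKM in germinating basal clove and at 38.0 FPKM in storage clove, where carried-over reads are not excluded. Asa2G05822.1 falls to 3.23 and 9.20 FPKM.

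The same changes were then compared between the tissues, in comparisons that share no library but share the estimate of the spread of each gene. At germination 5523 genes rose in both tissues, against 2450 for independent lists, and 6920 fell in both, against 3775. After median-ratio scaling the shared rises outnumbered the shared falls, 6936 (3363 for independent lists) to 5357 (2466). Asa2G05915.1 rose in both, to 2808.1 ± 1521.4 FPKM in basal and 3207.3 ± 734.9 FPKM in storage clove. Changes at germination correlated across genes at r = 0.65 (Spearman 0.63). Opposite directions were called for 1593 genes, against 6316 for independent lists. From enlarging to dormant the tissues shared little. There, 317 genes rose in both, against 310 for independent lists, 774 fell in both, against 645, and 1385 moved in opposite directions, against 993. Shared rises and falls were 561 and 565 after median-ratio scaling, against 550 and 436, and 530 and 663 after quantile normalization, against 532 and 461. The correlation across genes was 0.16 (Spearman 0.02). The count of 1091 genes that changed in the same direction in both tissues became 725 when every library was thinned to the same depth and 1639 when libraries were weighted by their distance from their group.

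**Figure D4:**
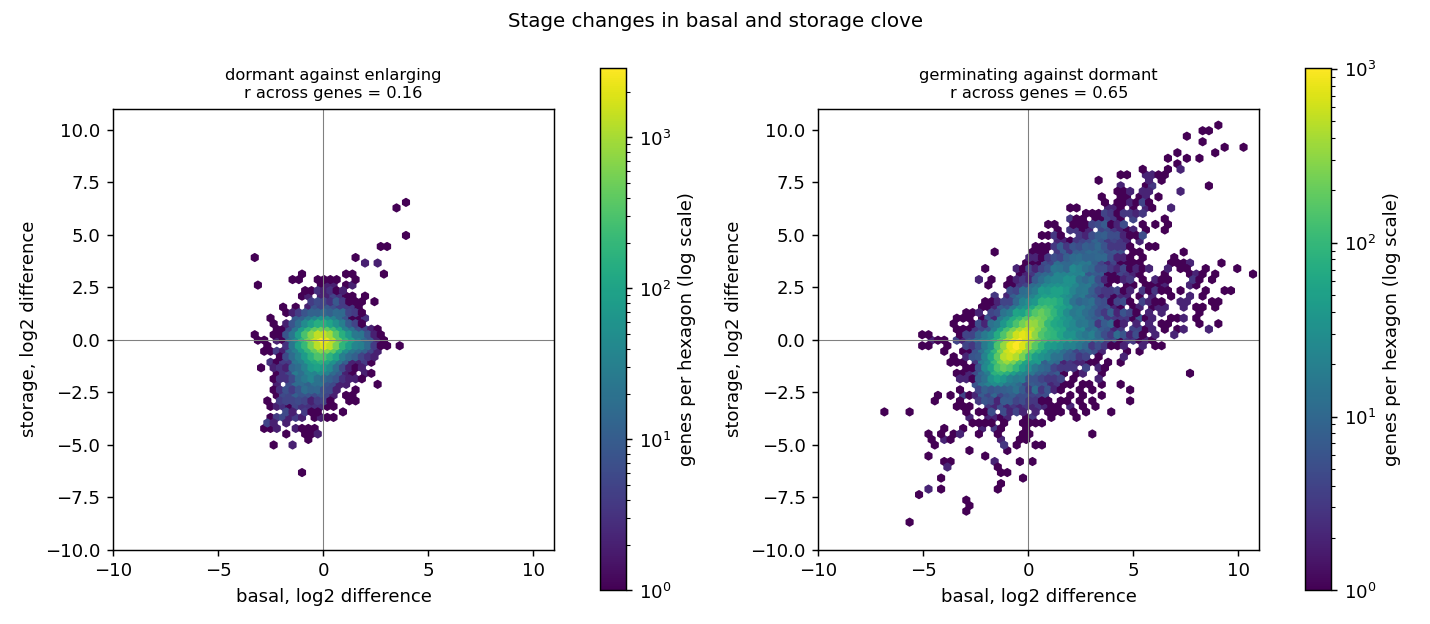
Change of each of 30530 genes on the log2(FPKM + 1) scale in basal clove (horizontal) and storage clove (vertical), from enlarging to dormant at the left and from dormant to germinating at the right, coloured by the number of genes per hexagon on a log scale. Changes at germination follow the diagonal (r = 0.65 across genes) and changes at dormancy hardly do (r = 0.16).

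A test of the interaction asked whether a stage change differed between the tissues. From enlarging to dormant it called 8720 genes, 5375 with the more positive change in basal clove and 3345 with the more positive change in storage clove. Asa7G03238.1 was one of them, since it fell by 3.15 (SE 0.34) in basal clove and rose by 3.90 (SE 0.34) in storage clove on the log2 scale. From dormant to germinating 13003 genes were called, 4126 with the more positive change in basal clove and 8877 with the more positive change in storage clove. Asa5G00575.1 was higher in germinating than in dormant clove of both tissues, at 2071.6 ± 501.2 FPKM in basal and 38.0 ± 4.97 FPKM in storage clove. Its values meet the limits set below for transcripts of germinating basal clove that may have been carried over. Whether it rose in storage clove itself is therefore open. The split depended on scaling in both tests. The share with the more positive change in basal clove was 61.6% at dormancy and became 48.8% after quantile normalization, and at germination it was 31.7% and became 49.9% after median-ratio scaling and 43.8% after quantile normalization. These scalings moved the median interaction from 0.10 to -0.02 at dormancy, and from -0.28 to -0.08 and -0.12 at germination.

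Germinating clove was also set against enlarging clove. In basal clove 21476 genes were called, 9094 higher and 12382 lower at germination, and in storage clove 16259, with 7384 higher and 8875 lower. Asa6G03213.1 fell in both tissues, from 1274.2 ± 203.1 to 1.01 ± 0.475 FPKM in basal and from 707.8 ± 72.2 to 3.43 ± 0.932 FPKM in storage clove. In both tissues together 5486 genes were higher and 7081 lower, against 2199 and 3599 for independent lists. Another 837 went in opposite directions, against 5638. The shared lists were 7146 higher (3404 for independent lists) and 4981 lower (2086) after median-ratio scaling, so which was longer depended on the scaling. After median-ratio scaling the share of calls that were higher at germination was 56.1% in each tissue, in place of 42.3% in basal and 45.4% in storage clove, with the median of all genes moved from -0.19 to 0.08 and from -0.07 to 0.04.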

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

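The counts of other splits of the libraries were chosen after the call counts were seen. In both steps between stages, the change in basal clove differed from the change in storage clove for many genes, by a test of the difference itself. From enlarging to dormant 8720 genes passed that test, and from dormant to germinating 13003 did. Among the 26 genes named by the rule, 19 passed it in at least 1 of the steps. The rule picks genes for a large difference in 1 comparison, which favours passing. Over all genes tested, 28.6% passed for the step to dormancy and 42.6% for the step to germination. The share that passed in at least 1 of the steps, the like measure for the 19, is not given here and cannot be below 42.6%. For 2 of the named genes the changes were called in opposite directions, both from enlarging to dormant. Asa7G03238.1 fell by 3.15 (SE 0.34) in basal clove and rose by 3.90 (SE 0.34) in storage clove, a difference of -7.06 (SE 0.48, limma adjusted p = 2.6e-07). Asa2G05822.1 fell by 1.36 (SE 0.20) in basal clove and rose by 1.01 (SE 0.20) in storage clove, a difference of -2.36 (SE 0.28, limma adjusted p = 1.8e-05). Both genes then fell in both tissues at germination, to group means under 10 FPKM.

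For the interactions, 100 splits of tissue labels within the stages compared were counted, the real one included. With the values as they stood, 6 of the 100 gave as many calls for the step to dormancy, the real one with 8720 and the highest of the others with 12821, and 1 of the 100 did for the step to germination, the real one with 13003 and the highest of the others with 12268. These counts do not bear on chance. A split that mixes the tissues puts the tissue effect into the spread, and one that keeps the labels of one stage and exchanges most of those of the other turns a difference of tissue effects into their sum. There were 11 splits of the latter kind for the step to dormancy and 9 for the step to germination, and they held the highest counts. The splits were therefore counted again after the additive effects of tissue and stage had been removed from the libraries compared, a test added after the first counts were seen. In each step 1 of the 100 splits then gave as many calls, the real one, with 8720 and 13003. The highest of the others gave 1 for the step to dormancy and 3537 for the step to germination, and 98 and 95 of the others gave none. A split that mixes the tissues now puts the interaction into the spread. A share of 1 in 100 is the smallest this number of splits can give, so it argues against chance without excluding it.

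In the 9 comparisons of 2 groups, 3 libraries against 3 make 10 splits, too few for a share under 0.05, and in each 1 of the 10 gave as many calls, the real one. For basal against storage clove the real and the highest other counts were 15724 and 2 when enlarging, 17615 and 0 when dormant, and 18457 and 177 when germinating. For dormant against enlarging they were 9615 and 0 in basal and 6185 and 1 in storage clove, for germinating against dormant 20998 and 0 in basal and 18234 and 0 in storage clove, and for germinating against enlarging 21476 and 1 in basal and 16259 and 1 in storage clove.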

How the results depend on the processing

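The voom weights, the thinning to equal depth and the joint removal of 2 libraries were chosen after the depths and library positions were seen. Over the 14 counts reported and 31 alternatives each, 417 counts stayed within 1.5 times the reported one, 16 fell below and 1 rose above that range. Requiring a change of at least 1 as well left 6123, 7857 and 7650 genes between the tissues (enlarging, dormant, germinating), 1877 and 1862 from enlarging to dormant (basal, storage), 9467 and 8276 from dormant to germinating, 11492 and 6284 from enlarging to germinating, and 3446 and 6586 for the interactions. It left 2691 genes in the overlap of the 3 tissue comparisons and 292 and 4372 in the overlaps of stage changes between tissues at dormancy and germination. These are subsets by construction. With voom weights 3626 genes were called in dormant against enlarging storage clove. The overlap of stage changes at dormancy was 1639 with array weights and 725 after thinning. The cause was not tested for these 3 values. No count left that range when 1 library was left out, or the 2 together. Of 840 refits of the named genes none changed direction, and 1 was no longer called (Asa7G02774.1 with voom weights, -4.27, adjusted p = 0.053). No pairing of the libraries by replicate number was seen, though this cannot exclude that libraries came from the same bulbs. Of 45 pairs with the same number, 3 had deviations that correlated above 0.1 (range -0.24 to 0.24). Of 18 libraries, 6 correlated best with their own number. With that number as a replicate block the calls went from 15724 to 14684, 17615 to 16824 and 18457 to 17673 between tissues, and from 6185 to 5762 in dormant against enlarging storage clove, with no count moved by over 1.5 times. The model pools the spread of a gene over groups with unlike replicates. The chi-square per gene was 14.14 to 65.92 in basal germinating and 2.68 to 3.62 in storage dormant clove. Fits on only the groups compared called 15824 genes in place of 18457 between tissues at germination. For dormant against enlarging they called 12128 in place of 9615 in basal and 4571 in place of 6185 in storage clove. The set tests with an estimated correlation were not run, since no gene list could be formed. Depth limits low values most in dormant storage clove, where 3 reads on a 1 kb coding length are 0.419 to 0.459 FPKM.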

Other observations

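All tests here were chosen after the report's comparisons had been seen, and those on carried-over transcripts after their values had been seen. With the deposited values, much of what changed in storage clove at dormancy changed back at germination. Of the genes called at the first step, 3070 fell and then rose, against 1326 for independent lists, and 1497 rose and then fell, against 543. Only 103 rose at both steps and 263 fell at both, against 577 and 1248. These lists were counted with the deposited values only. At the first step 4309 genes fell and 1876 rose with those values. The numbers were 3183 and 3044 after median-ratio scaling and 2889 and 3025 after quantile normalization. The 3070 genes that fell and then rose exceed all falls called after quantile normalization. Asa7G03238.1 was one that rose and then fell, from 133.9 ± 31.2 FPKM in enlarging to 2068.5 ± 719 in dormant and 6.37 ± 0.843 in germinating storage clove (mean ± SD, n = 3), and Asa7G06203.1 another, from 0.611 ± 0.808 to 147.3 ± 8.56 and 36.8 ± 17.1 FPKM. Basal clove showed little of this, with 2483 genes rising and then falling, against 2153, 877 falling and then rising, against 1193, 2762 falling at both steps, against 1952, and 1052 rising at both, against 1315. Both steps use the dormant libraries, so chance alone gives a negative relation. Across genes the covariance of the changes was -0.369 in storage clove (r = -0.53), against -0.027 in simulated unchanged groups and -0.034 from the spread of the dormant storage replicates. In basal clove it was -0.061 (r = -0.09), against -0.027 and -0.015. Simulated unchanged groups gave a mean of 0 genes in each list over 20 simulations, but a gene must be called at both steps to enter one, so that value says little about the excess. The 3 dormant libraries cannot be divided into sets of at least 2, so how much of the excess over independent lists comes from sharing them was not settled, and anything else particular to the dormant storage libraries, which are also the shallowest, enters both steps.

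Basal clove held more detected genes than storage clove at equal depth. With every library thinned to 6539512 reads, genes with at least 5 reads numbered 26417 ± 130.7 in basal and 25034 ± 254.1 in storage enlarging clove, 26295 ± 191.9 and 24139 ± 266.9 at dormancy, and 26800 ± 259.0 and 25650 ± 392.9 at germination (mean ± SD, n = 3). The lowest basal library had 26141 and the highest storage library 26101. The mean difference of 1562.8 genes had p = 0.00025 in an exact two-sided permutation test within stages (8000 arrangements), the smallest p it can give. Genes present in one tissue and nearly absent from the other were also mostly basal. At dormancy 318 genes had at least 20 thinned reads in each basal library and at most 3 over the storage libraries, and 15 genes had the reverse. When enlarging the numbers were 65 and 19, with storage enlarging replicate 2, which lay toward the basal libraries, among the libraries counted. When germinating they were 220 and 1. Over the 3 stages together, 3 genes passed these limits in all basal against all storage libraries, and 0 had the reverse.

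Transcripts of germinating basal clove were seen at a low level in libraries taken before germination, here mainly in 4 storage libraries picked for their values. In 37 genes at 100 FPKM or more in basal germinating clove, with at most 0.5% of that in the other basal groups and 5% in storage germinating clove, the median level was 0.258% and 0.223% of the basal germinating level in storage enlarging replicates 2 and 3, and 0.362% and 0.311% in storage dormant replicates 2 and 3. It was 0% and 0.022% in replicate 1 of the 2 groups. Basal libraries held them too, within the limit set on them, at 0.248%, 0.170% and 0.136% when enlarging and 0.105%, 0.057% and 0.084% when dormant (replicates 1, 2 and 3). Basal enlarging replicate 1 resembled the 4 storage libraries, with a Spearman correlation of 0.80 and quartiles 1.95 times apart, and in the other basal libraries the quartiles were over 5 times apart. The quartiles of the share were less than 2 times apart in 4 of the 6 storage libraries taken before germination, and the Spearman correlation with the basal germinating level reached 0.89 but was 0.32 in storage enlarging replicate 1. In storage germinating replicates 1, 2 and 3 the quartiles were 2.74, 1.61 and 4.30 times apart and the correlations 0.83, 0.93 and 0.79. Reads or RNA of basal germinating samples carried over and the genes' own low expression in storage clove are therefore both open, since libraries with an even share and libraries without one were found and the former were picked by looking at these values. A first version of the test covered only the 4 named above. Low storage values of genes such as Asa0G00573.1, at 4.63 ± 2.32 FPKM in dormant storage clove and 2128.4 ± 166.7 in germinating basal clove, may hold carried-over reads, and folds against them would then understate the difference.

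Storage enlarging replicate 2 lay toward the basal libraries. Of 125 genes restricted to basal clove at dormancy, 92.8% were higher in it than in the mean of its 2 replicates, and their median level was 8.29% of that in basal enlarging clove, against 2.81% and 2.22% in replicates 1 and 3. These genes were also required to be much lower in the mean of storage enlarging clove, replicate 2 included. Genes raised most in replicate 2 could thus be left out, and the quartiles below were taken after that choice. Reads leaking from every other library are argued against, since genes restricted to germinating libraries exceeded the replicates by a median of only 0.1% of their germinating level, against 4.40% of the basal level for the basal-restricted genes. Basal tissue of the average basal enlarging profile is argued against too, if the noise was no larger than between the other 2 replicates. The test asked that the excess be a similar share of the basal level for all genes, and its quartiles were 1.67% and 8.24%, 4.92 times apart (95% bootstrap interval over genes 3.53 to 6.76), against a bound of 3 set beforehand. The difference between the other 2 replicates gave the noise, and a common share with that noise would have put the quartiles 1.41 times apart. Those replicates held these genes at 2.81% and 2.22% of the basal level, against 8.29% in replicate 2. The noise at the level of replicate 2 may be larger, and 1.41 may be too low. The noise estimate and the interval were added after the quartiles were seen, and an earlier reading had left this open. A part of the basal clove with another profile was not tested, and the cause stays open.

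Basal germinating replicate 3 lay toward the storage libraries. Of 37 genes restricted to storage clove at dormancy, 91.9% were higher in it than in the mean of its 2 replicates. These genes were also required to be lower in the mean of basal germinating clove, replicate 3 included, than in storage germinating clove. Genes raised most in replicate 3 could thus be left out, which bears on the quartiles below. The other tissue was allowed up to 10% of the level at dormancy for these genes, against 2% for the basal-restricted genes above. In replicate 3 their median level was 28.5% of that in storage germinating clove, against 16.36% and 12.05% in replicates 1 and 2. The excess had quartiles of 5.94% and 21.81% of the storage germinating level. The quartiles were 3.67 times apart, with a 95% bootstrap interval of 2.20 to 9.83, also added later, that includes the bound of 3, so storage tissue in the sample stays open. In 124 genes that rose at germination in storage clove and stood as high in the other basal libraries as in storage clove, replicate 3 was higher still, by a median of 0.24 on the log2 scale (quartiles 0.09 and 0.53). The same measure was -0.07 for replicate 1 and -0.53 for replicate 2. A mixture with storage tissue of the average profile would leave it near 0, so a candidate explanation is that this sample was further along in germination. The value of 0.24 is only just above the 0.2 set beforehand, and replicate 2 departed further, in the other direction. Each replicate was set against the other 2 on its own set of genes. The measure therefore does not tell a replicate 3 that was ahead from a replicate 2 that was behind, or from the spread among replicates.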
